A study of Mus musculus with 10 samples.

How the data were processed

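RNA from 10 cochlea samples of male mice aged 9 months, 5 wild-type and 5 Polg D257A, had been hybridised to mouse Affymetrix arrays of 45101 probe sets as biotin-labelled RNA, per the labels' protocols. The deposited values are linear array intensity, 1 value per probe set and array, made with GCOS 1.3, per the submitters' processing notes. Background correction, probe summary and scaling target are not given in the sources used here. From the values themselves, the trimmed mean (trim 2%) is 1494 to 1496 on each array, so the authors' scaling was kept. Median signals were 551.7 to 649.3. Detection calls and scan dates were not used here, so no batch could be tested. Values for 64 control probe sets were filled for D257A replicate 5 only, and these were left out on all arrays. The labels number the samples 1 to 5 within each group and do not say outright that each is a separate animal. The design text says that no replicates were done, so pooled or repeated samples cannot be ruled out. In what follows n counts arrays, and p-values of single genes and of permutation tests measure the spread between these samples. The p-values of the list test camera compare a list with other genes under an assumed correlation. They do not measure that spread alone.

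Probe sets were named from the platform table: of 45037 probe sets without controls, 34945 had 1 gene, 932 several and 9160 were unnamed here. A gene was represented by its brightest probe set over all arrays, and probe sets with several genes or none were not named. Of 174 genes selected by the rule below, 69 had several tested probe sets and 17 of these had 1 or more of the opposite sign.

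Signals were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. The fraction 0.5 of probe sets with the higher mean log2 signal over all arrays was tested (22518, from a signal of about 577 upwards). A linear model with group as its only term was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with 8 residual degrees of freedom, two-sided p-values and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. Adjusted p-values given for a gene come from this fit unless another setting is named.

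Of 41 gene lists fixed from textbook knowledge, 40 had at least 3 measured genes and were tested. The list of transcripts encoded by mitochondrial DNA had none under the names used and was not analysed here; ND5, found under another name, was given alone. The lists named 950 members in all, 691 genes had a tested probe set, and 49 genes stood in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The estimated correlation kept 1 of 7 calls; fry, which does not compare a list with other genes, called 5 in a common direction and 21 in either direction. A list score is the mean over members of log2 signals centred per gene, compared between groups by a two-sided exact permutation test. Another 7 lists were written after some values had been seen, and serve only the tests of the closing part.

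The named genes were, among called genes whose groups do not overlap, the 12 with the largest log2 fold change in each direction, up to 4 members of each list with the smallest unadjusted p, and Polg. Of these 174 genes 55 were called, 18 higher and 37 lower, and the text gives all called ones with a few others. The groups, the model, the lists, this rule and all alternatives but 1 were fixed before the data were examined. Of the 55 called genes, 30 kept their call in each of the 10 fits that left out 1 array and 25 lost it in at least 1.

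The alternatives were a pseudocount of 1 or 64, arrays centred on the median, quantile normalization, no filter, the brightest 30%, no intensity trend, array weights, the replicate number as a block, each array left out in turn, other thresholds and the mean over a gene's probe sets. Leaving out the arrays least correlated with their own group, wild-type replicate 3 (mean r 0.914) and D257A replicate 2 (0.89), was added after seeing the data. The scripts were tested on simulated data: of 22518 probe sets, with 200 changed, 56% of the 1-unit and 93% of the 2-unit log2 changes were recovered and 7.45% of calls were false. In a simulation over 11871 genes drawn independently of each other, 1 list shifted by 0.5 was recovered and 0 of 39 others were called. Members of some real lists are correlated (estimated at 0.785 for muscle and 0.473 for neutrophil markers). The simulation therefore does not bound false list calls on these arrays. Gene ontology categories, used in the study's design, were not analysed here.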

Results

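Cochlear RNA from male mice aged 9 months was profiled on 10 arrays, 5 from wild-type mice and 5 from mice with the D257A form of Polg. Polg encodes the catalytic subunit of the mitochondrial DNA polymerase, and the D257A change removes its proofreading activity, so that mutations accumulate in mitochondrial DNA. The cochlea is the hearing organ of the inner ear. The trimmed mean signal lay between 1494 and 1496 on all arrays, and the correlation of log2 signals between pairs of arrays ranged from 0.854 to 0.951. The first principal component held 36.1% of the variance and set D257A replicate 2 (score 96.93) and wild-type replicate 3 (45.58) apart from the other arrays of their groups. The number of arrays limits the precision of every value below.

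The comparison asked which cochlear transcripts differ when mitochondrial DNA mutations accumulate. The Polg transcript did not pass the test: its signal was 2792 ± 477.6 in wild-type and 2751 ± 542.4 in D257A cochleae (SD, n = 5 each), with single arrays from 1972.8 to 3223.6 and from 2083.7 to 3437.6 and a limma adjusted p of 0.966. The mutation is a single amino acid change, so this level does not check the genotype labels. The sign of the Polg difference (log2 fold change -0.02) turned to 0.02 under quantile normalization.

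Genes of skeletal muscle, of secretory and squamous epithelia, of fat and of collagen matrix were among those that fell in D257A cochleae, and the largest falls were those of Myh2, Lipf, Dmbt1 and Bpifb1. Other genes rose, with Lamp5, Mtm1, Cbln4 and Rbfox2 among the genes with the largest rises that kept their call whichever array was left out. Of 22518 probe sets tested, 513 passed an adjusted p of 0.05 in limma, 233 higher and 280 lower in D257A (45.4% higher). By gene, 78 were higher and 197 lower among 11871 tested. More than 2-fold changes were seen in 146 of the higher and 208 of the lower probe sets. The 5 D257A values lay wholly outside the wild-type range for 1162 probe sets (5.16% against 0.794% by chance), including 453 of the 513. When each array was centred on its median over all probe sets, which moved the median log2 fold change of the tested probe sets from -0.000544 to -0.101, the split was 174 higher and 479 lower (26.6% higher). It turned round with no filter on dim probe sets (301 higher, 290 lower, 50.9% higher) and without D257A replicate 4 (296 higher, 205 lower, 59.1% higher). The count fell to 168 without wild-type replicate 2, 277 without wild-type replicate 4, 177 without wild-type replicate 5, 299 without D257A replicate 1 and 323 without D257A replicate 5.

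**Figure D1:**
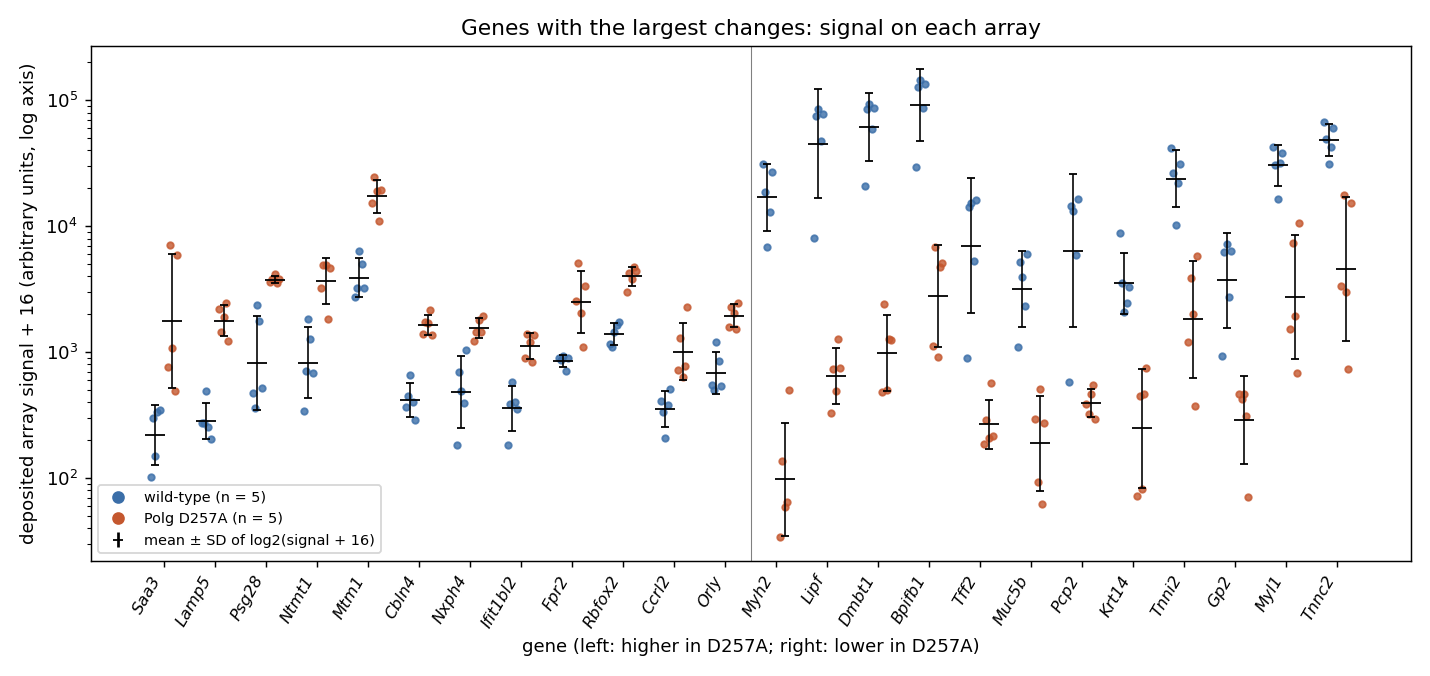
Deposited array signal plus 16 on a log axis for the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap. Points are arrays (5 wild-type, 5 D257A) and bars give the mean ± SD of log2 values; Myh2 is at 6820.2 or above on every wild-type array and at 486.4 or below on every D257A array.

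Skeletal muscle genes formed the group with the largest difference. All 22 measured muscle markers had negative log2 fold changes, with a median of -2.71, and 10 of them were called (21 adjusted over the list alone). Myh2, the myosin heavy chain of fast oxidative fibres, fell from 19370 ± 9953 to 143.4 ± 195.5 (SD, n = 5 each; log2 fold change -7.44, SE 0.63, adjusted p = 0.000179). Its D257A signals, from 18 to 486.4, lay below the lower edge of tested mean signals (577) and were not shown to be above background, so the size of its fall and its rank are uncertain. Tnni2, a fast troponin, fell from 26360 ± 11620 to 2635 ± 2179 (log2 fold change -3.71, adjusted p = 0.0103). Myl1, a fast myosin light chain, fell from 32000 ± 10060 to 4406 ± 4346 (adjusted p = 0.0148). Casq1, a calcium-binding protein of the sarcoplasmic reticulum, and Actn2, of the Z-disc, fell as well (log2 fold change -2.28 and -2.45, adjusted p = 0.00648 and 0.0103). The fall was uneven between arrays: the mean centred log2 score of the list was 0.538 in D257A replicate 5, above that of wild-type replicate 3 (0.156), and -2.94 in D257A replicate 4. The creatine kinase Ckm, chosen after its values were seen, measured 58214.5 in D257A replicate 5 against 38480 ± 19480 in wild-type and 1011.9 in D257A replicate 4 (log2 fold change -2.49, adjusted p = 0.174). The list passed camera (adjusted p = 4.29e-21), but not when the correlation among its members was estimated (adjusted p = 0.258 with an estimated correlation). Tnnc2 fell by 3.41 on the log2 scale, a call lost in 6 of 10 fits that left out 1 array, with an adjusted p of up to 0.0789 without wild-type replicate 5.

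Several genes of glandular and mucosal epithelia fell as well. Among 16 measured markers of middle ear and airway epithelium, 15 were negative, 6 were called lower (10 adjusted over the list alone) and the median log2 fold change was -0.633. Bpifb1, a secreted antimicrobial protein, fell from 104400 ± 47260 to 3737 ± 2616 (SD, n = 5 each; log2 fold change -5.03, SE 0.60, adjusted p = 0.00185), and the gel-forming mucin Muc5b from 3722 ± 2038 to 230.8 ± 179.1. The basal epithelial keratins Krt5 and Krt14 fell with log2 fold changes of -2.24 and -3.83 (adjusted p = 0.00207 and 0.0103). Outside the list, Lipf (gastric lipase) fell from 58870 ± 31790 to 703.2 ± 360.1, Dmbt1 (a mucosal scavenger receptor) from 69230 ± 30000 to 1174 ± 793, Tff2 (a mucus-associated trefoil peptide) from 10390 ± 6863 to 278.3 ± 159.4 and Gp2 from 4681 ± 2720 to 331 ± 166.7, each with an adjusted p of at most 0.0105. The D257A means of Muc5b, Krt14, Tff2, Gp2 and Pcp2 also lay below 577, so the sizes of their falls are uncertain in the same way. Wild-type replicate 1 had the lowest wild-type signal for Lipf, Dmbt1, Tff2 and Gp2, for example 8034.8 for Lipf against at least 47957.9 on the other wild-type arrays. Pcp2, a Purkinje cell transcript of the cerebellum, fell from 10130 ± 6690 to 389.1 ± 106.7 (adjusted p = 0.0166), was again lowest among wild-type arrays in replicate 1 (563.6), and lost its call in 2 of 10 fits that left out 1 array (0.0524 without wild-type replicate 5). The epithelial list passed camera (adjusted p = 1.08e-08; adjusted p = 0.105 with an estimated correlation).

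The extracellular matrix list was also lower. Of 27 measured members, 23 were negative and 6 were called lower (8 adjusted over the list alone), with a median log2 fold change of -0.304. Col3a1, the chain of type III collagen, fell from 12220 ± 1170 to 5952 ± 1117 (SD, n = 5 each; log2 fold change -1.05, SE 0.15, adjusted p = 0.00486). The small proteoglycan gene Bgn fell from 15960 ± 1459 to 8419 ± 752.2 (log2 fold change -0.92, adjusted p = 0.00444). Postn fell from 4678 ± 742.9 to 2340 ± 499.4 and Col1a1 from 19390 ± 7624 to 4922 ± 2585 (adjusted p = 0.0159 and 0.0196), and these lost their calls in 1 and 3 of 10 fits that left out 1 array (up to 0.0572 without wild-type replicate 2 and 0.0661 without wild-type replicate 5). The list score of every D257A array (-0.256 to -0.143) lay below that of every wild-type array (0.119 to 0.308). This list alone passed camera both with the preset correlation (adjusted p = 2.33e-05) and with an estimated one (adjusted p = 0.0291 with an estimated correlation), and also fry (adjusted p = 5.26e-05). Fry also called the epithelial, muscle, platelet and myelin lists (adjusted p = 0.00202, 0.0367, 0.0367 and 0.0477), but not the adipocyte and neutrophil lists (0.103 and 0.145). The epithelial and platelet scores separated the groups as well. Muscle and epithelial markers fell in the same comparison, as given above.

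Fat, cartilage and bone markers included further called genes. Among 11 adipocyte markers, 10 were negative and 3 were called lower (4 adjusted over the list alone), with a median log2 fold change of -0.573. The hormone gene Adipoq fell from 8197 ± 1814 to 2760 ± 844 (SD, n = 5 each; adjusted p = 0.00498), the lipid droplet gene Cidea from 10650 ± 2208 to 4070 ± 956.3 (adjusted p = 0.00444) and the desaturase gene Scd1 from 41800 ± 6417 to 18020 ± 4679 (adjusted p = 0.0103). This list passed camera (adjusted p = 0.00358; adjusted p = 0.582 with an estimated correlation), though not without D257A replicate 1 (adjusted p = 0.0662). Its scores were -1.11 and -0.923 in D257A replicates 1 and 3, while those of D257A replicates 2, 4 and 5 (0.121, 0.105 and 0.347) lay within the wild-type range of -0.03 to 0.453. In cartilage markers 2 of 12 were called lower and 1 higher: Cytl1 fell from 5923 ± 1779 to 2248 ± 198.9, Comp from 4756 ± 1754 to 1800 ± 475.4, and the lubricin gene Prg4 rose from 3768 ± 292.6 to 5885 ± 803.9. The calls of Comp and Prg4 were lost in 3 and 9 of 10 fits that left out 1 array (up to 0.0755 and 0.135, both without wild-type replicate 2). The cartilage list (median -0.366, adjusted p = 0.122; 0.0376 with no filter on dim probe sets) and the bone list (15 measured, Col1a1 called, median -0.302, adjusted p = 0.232) did not pass.

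Among the higher lists, neutrophil genes had the largest median. Of 19 measured neutrophil and granule markers, 16 were positive with a median log2 fold change of 0.733, 2 were called higher and 1 lower (12 and 2 adjusted over the list alone). The granule enzymes Mpo and Ctsg rose from 3679 ± 779.3 to 8257 ± 3003 and from 916.8 ± 242.6 to 2351 ± 867.1 (SD, n = 5 each; adjusted p = 0.0309 and 0.0337). Ltf, which encodes lactoferrin and is also secreted by glands and counted in the epithelial list, fell from 41370 ± 22350 to 8575 ± 2969 (adjusted p = 0.0306). These 3 calls were lost in 7, 6 and 6 of 10 fits that left out 1 array, with adjusted p of up to 0.0825 without wild-type replicate 4, 0.0846 without wild-type replicate 5 and 0.0939 without wild-type replicate 2. The list passed camera (adjusted p = 3.35e-06; adjusted p = 0.559 with an estimated correlation), while its array scores overlapped: D257A replicate 4 scored -0.517 and the D257A replicates 2 and 5 scored 0.547 and 0.809, with an exact permutation p of 0.103. Platelet and megakaryocyte markers were positive in 12 of 13 (median 0.27) with no gene called (2 adjusted over the list alone), and passed camera (adjusted p = 0.00358; adjusted p = 0.23 with an estimated correlation), though not among the brightest 30% of probe sets (0.116). Gp1bb, a subunit of the platelet von Willebrand factor receptor, measured 1053 ± 98.19 and 1621 ± 238.8 (adjusted p = 0.0709). Erythroid markers did not pass (27 measured, 20 negative, median -0.12, adjusted p = 0.393).

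Schwann cell and myelin genes were the remaining higher list. Of 17 measured members 13 were positive, 2 were called higher (4 adjusted over the list alone) and the median log2 fold change was 0.299. Mobp, a myelin protein of oligodendrocytes in the central nervous system, rose from 5599 ± 1999 to 13690 ± 4855 (SD, n = 5 each; log2 fold change 1.28, adjusted p = 0.0466). Egr2, a transcription factor of myelinating Schwann cells that also responds early to stimuli, rose from 2733 ± 242.4 to 4650 ± 767.3 (log2 fold change 0.75, adjusted p = 0.0279). Their calls were lost in 9 and 5 of 10 fits that left out 1 array (up to 0.109 without wild-type replicate 4 and 0.0941 without wild-type replicate 2). Mbp, myelin basic protein, measured 69850 ± 9644 and 92130 ± 4463 (adjusted p = 0.113), and 1 of its 8 probe sets had the opposite sign. Among peripheral myelin genes of the list, Pmp22, Drp2 and Cldn19 changed little (log2 fold change 0.0198, -0.0119 and 0.0415). Mal, Ncmap and Gjb1 had values of 0.299, 0.313 and 0.236 without a call. The list therefore does not show a rise of Schwann cell genes in particular. The list passed camera (adjusted p = 0.00603; adjusted p = 0.162 with an estimated correlation). Its score was -0.224 in D257A replicate 2, below all wild-type scores. Over the 7 lists that passed, 6 lost their call with an estimated correlation, and 42 of 100 splits of the arrays into 5 and 5, the real one included, gave at least 7 lists.

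**Figure D2:**
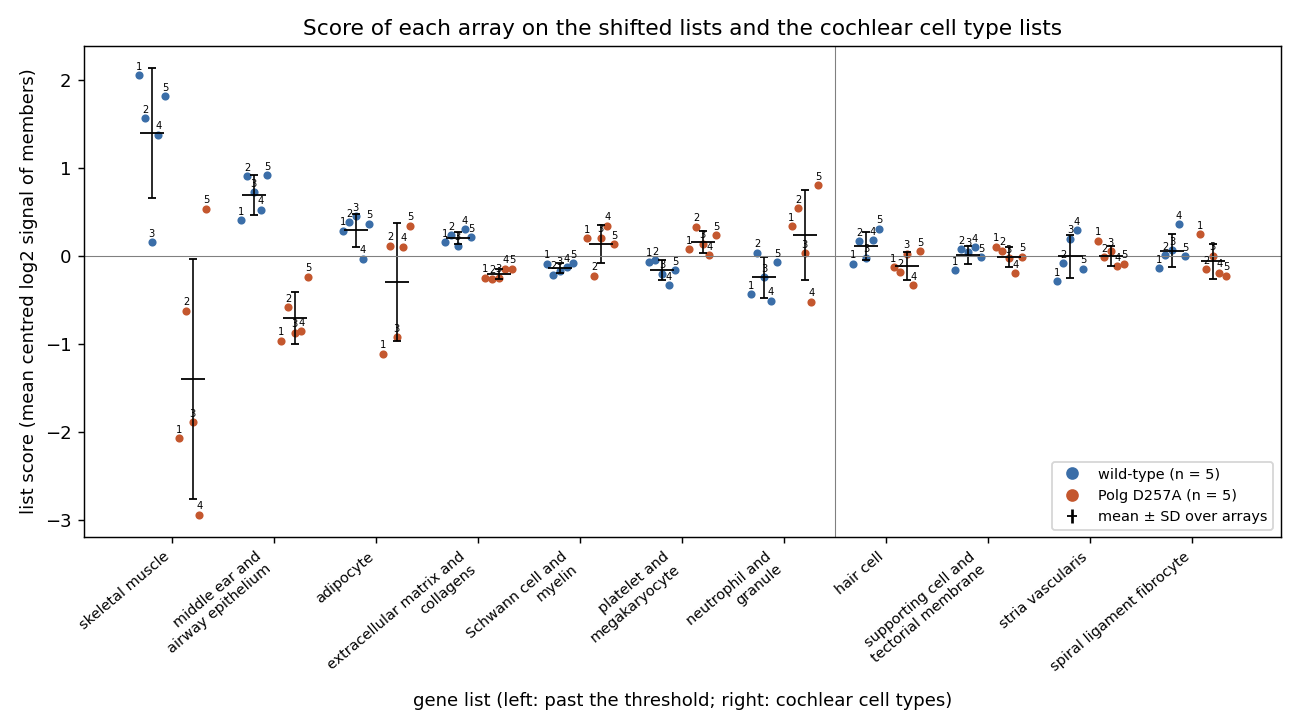
Score of each array (mean centred log2 signal of the list's members) on the 7 lists past the threshold and the 4 lists of cochlear cell types, with small digits for replicate numbers and bars for mean ± SD. The muscle scores reach from -2.94 to 2.06, while extracellular matrix scores lie within -0.256 to 0.308. The extracellular matrix, epithelial and platelet scores separate the groups.

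The genes with the largest rises were chosen among called genes whose groups do not overlap. The wild-type means of Saa3, Lamp5, Cbln4, Nxph4, Ifit1bl2 and Ccrl2 lay below 577 and were not shown to be above background. The sizes of their rises and their ranks are therefore uncertain. Lamp5, a lysosome-associated membrane protein of some neurons, rose from 284.1 ± 111.7 to 1823 ± 507.4 (SD, n = 5 each; log2 fold change 2.64, SE 0.27, adjusted p = 0.000728). Mtm1, the phosphoinositide phosphatase myotubularin, rose from 4112 ± 1522 to 17900 ± 5096 (log2 fold change 2.14, SE 0.27, adjusted p = 0.0021). Cbln4, a secreted synaptic protein, rose from 418.1 ± 139.1 to 1655 ± 320.7, and the splicing regulator Rbfox2 from 1399 ± 284.3 to 4029 ± 668.8. Orly rose from 715.2 ± 303.8 to 1969 ± 406.3 and Ifit1bl2 from 366 ± 140.8 to 1124 ± 260.3 (adjusted p = 0.0127 and 0.0145). These 6 genes kept their call in every fit that left out 1 array. The acute-phase gene Saa3 rose from 231 ± 112.5 to 3066 ± 3185, with 7096.6 and 5938.8 in D257A replicates 2 and 5 and 472.1 in replicate 4. Its adjusted p of 0.0475 was lost as a call in 9 of the 10 fits that left out 1 array, with values of up to 0.104 without D257A replicate 5. Psg28, Ntmt1, Nxph4, Fpr2 and Ccrl2 rose by between 1.52 and 2.20 on the log2 scale and lost their calls in 6, 3, 8, 6 and 9 of those fits, with adjusted p of up to 0.0858 without wild-type replicate 5, 0.0669 without wild-type replicate 5, 0.0946 without wild-type replicate 4, 0.0795 without wild-type replicate 2 and 0.122 without wild-type replicate 2.

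Nuclear genes of oxidative phosphorylation did not pass as lists, with exceptions in other settings for complexes I and IV. None of the 32 measured complex I subunits was called; 23 were positive, and the median log2 fold change was 0.162 (camera adjusted p = 0.133). The list passed without wild-type replicate 1 (adjusted p = 0.0226) and without D257A replicate 3 (0.0018), and with the mean of each gene's probe sets (0.022), but reached 0.511 with array weights. Ndufa9 measured 10530 ± 2729 in wild-type and 6238 ± 3492 in D257A (SD, n = 5 each; adjusted p = 0.209). Complexes II and III had a median of 0.0421 but a negative mean (-0.0474), and the median turned negative under both other scalings (14 measured, adjusted p = 0.936). Complex IV had a median of 0.199 and a mean of -0.0531. It included Cox6a2, a heart and muscle isoform, which measured 11730 ± 3764 and 3540 ± 3785 (adjusted p = 0.0594). The complex IV list had an adjusted p of 0.232, and between 0.0464 (without D257A replicate 3) and 0.778 when 1 array was left out. ATP synthase subunits (15 measured, median 0.0862, adjusted p = 0.516), the mitochondrial ribosome (43 measured, median 0.0627, adjusted p = 0.499) and genes of mitochondrial DNA maintenance and expression (21 measured, median 0.0383, adjusted p = 0.574) held no called gene, and the medians of all 3 turned negative when arrays were centred on the median. Twnk, the mitochondrial replicative helicase, measured 1890 ± 150.4 and 1316 ± 328.6 (adjusted p = 0.16). The only transcript of mitochondrial DNA with a named probe set here, ND5, measured 66020 ± 10670 and 67980 ± 16480 (adjusted p = 0.972 in the fit with no filter on dim probe sets).

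Other metabolic lists also held few calls. The tricarboxylic acid cycle (19 measured, median -0.0627, adjusted p = 0.518) and mitochondrial chaperones and proteases (14 measured, median -0.039, adjusted p = 0.779) had no called member. Fatty acid oxidation genes were negative in 16 of 18 (median -0.184) without a called gene, and the list had an adjusted p of 0.145, or between 0.041 (without D257A replicate 5) and 0.396 when 1 array was left out. It passed with no filter on dim probe sets (0.0376), with array weights (0.0235) and without both least correlated arrays (0.0185). Glycolysis (18 measured, median -0.11, adjusted p = 0.328) held 2 genes called lower, Eno3 and Pgam2, which are the muscle isozymes of enolase and phosphoglycerate mutase. Eno3 fell from 17440 ± 7730 to 2761 ± 1831 and Pgam2 from 5615 ± 3078 to 710.9 ± 781.7 (SD, n = 5 each), and the call of Pgam2 was lost in 7 of 10 fits that left out 1 array (up to 0.0864 without wild-type replicate 5). Among 21 integrated stress response and serine-folate genes, Nupr1 fell from 10560 ± 2887 to 4311 ± 2138 (adjusted p = 0.0409), and Psat1, an enzyme of serine synthesis, measured 3519 ± 505.7 and 6127 ± 1492 (adjusted p = 0.0539). That list had a median of 0.143 and an adjusted p of 0.339. Of 22 antioxidant enzymes, Txnrd2, the mitochondrial thioredoxin reductase, fell from 1292 ± 254.3 to 526 ± 235.9 (adjusted p = 0.0404). The D257A mean of Txnrd2 lay below 577, so the size of its fall is uncertain. The median of the antioxidant list was -0.0475, its mean 0.0232 and its adjusted p 0.574. The Nupr1 and Txnrd2 calls were lost in 7 and 6 of 10 fits that left out 1 array (up to 0.119 without wild-type replicate 2 and 0.116 without wild-type replicate 5).

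Genes of cell death and cell division did not shift as lists. None of 23 p53 targets and apoptosis genes was called (median -0.0418, adjusted p = 0.886); Perp, a p53 target at desmosomes, measured 3490 ± 568 and 2350 ± 298.7 (SD, n = 5 each; adjusted p = 0.0968). None of 21 cell cycle genes was called (median -0.0654, adjusted p = 0.936). Immediate early genes had 13 of 19 positive (median 0.0955, negative when arrays were centred on the median), with Egr2 called, and an adjusted p of 0.0762. That list passed without wild-type replicate 2 (0.0406), wild-type replicate 5 (0.0207), D257A replicate 1 (0.0137) and D257A replicate 4 (0.031), and with the mean of each gene's probe sets (0.0324), but reached 0.26 without D257A replicate 2. Circadian clock genes had no call (14 measured, median -0.123, adjusted p = 0.53).

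The 4 lists of cochlear cell type markers had medians between -0.102 and 0.0998. Hair cell markers (10 measured, 8 negative, median -0.101, mean -0.223, adjusted p = 0.328) and supporting cell and tectorial membrane markers (15 measured, median 0.0998, mean -0.0235, adjusted p = 0.875) had no called gene. Adjusted over the list alone, 1 hair cell marker was called lower. The hair cell marker with the smallest p, Pvalb, which is also a muscle marker, measured 40070 ± 9435 and 21690 ± 6308 (adjusted p = 0.0594). Myo7a, the unconventional myosin of hair cell stereocilia, measured 1519 ± 324.5 and 1094 ± 207.3 (SD, n = 5 each; adjusted p = 0.262), and the gap junction gene Gjb2 27190 ± 5286 and 22330 ± 3174 (adjusted p = 0.428). Spiral ligament fibrocyte markers had no call (16 measured, median -0.102, adjusted p = 0.574). In the stria vascularis, the epithelium that generates the endocochlear potential, 1 of 16 markers was called: Kcnj10, the potassium channel Kir4.1, which glial cells also express, rose from 2281 ± 753 to 5336 ± 661.2 (log2 fold change 1.26, SE 0.20, adjusted p = 0.00872). It was also the only call among 30 deafness genes. The stria list (median -0.0913, mean 0.00595, adjusted p = 0.922) and the deafness list (median -0.04, mean 0.0482, adjusted p = 0.499) did not pass. The sign of the supporting cell median turned negative when arrays were centred on the median.

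The remaining lists, of neuronal, immune and vascular genes, did not pass with the settings used throughout. Neuron markers had no call (25 measured, median 0.127, adjusted p = 0.574). Of 22 genes of synaptic transmission 14 were negative (median -0.177, adjusted p = 0.145, or 0.0255 with no filter on dim probe sets) and 2 were called lower (5 adjusted over the list alone). The glutamate receptor gene Gria2 fell from 5346 ± 1569 to 2281 ± 595.9 and the vesicle gene Vamp2 from 8675 ± 1278 to 4488 ± 1398 (SD, n = 5 each). Another of the Vamp2 probe sets had the opposite sign, and these calls were lost in 4 and 5 of 10 fits that left out 1 array (up to 0.0775 and 0.0871, both without wild-type replicate 5). As with Pcp2, wild-type replicate 1 had the lowest wild-type signal for Gria2 (3200.8) and for Vamp2 (7071.2). In the complement and antigen presentation list (19 measured, median -0.153, adjusted p = 0.122; from 0.0311 without D257A replicate 4 to 0.588 without D257A replicate 2), Cd74, the class II invariant chain, fell from 11020 ± 1881 to 5183 ± 1029 (adjusted p = 0.0101) and C1s1 from 1438 ± 239.9 to 587.5 ± 242.5 (adjusted p = 0.0272), the latter call being lost in 4 of 10 such fits (up to 0.082 without wild-type replicate 5). Adjusted over that list alone, 4 members were called lower. Jchain, which joins secreted immunoglobulins, was the only called gene of 8 B cell and plasma cell markers and fell from 2925 ± 475.1 to 1097 ± 299.6 (adjusted p = 0.00413; list median -0.253, adjusted p = 0.232). Macrophage and monocyte markers had a median of 0.151 (18 measured, adjusted p = 0.367), yet the lysozyme genes Lyz2 and Lyz1, expressed in myeloid cells and also in glands, fell from 70020 ± 25520 to 14300 ± 3485 and from 82030 ± 25920 to 28940 ± 7636. The Lyz1 call was lost in 2 of 10 such fits (up to 0.0516 without wild-type replicate 5). Slc25a37, mitoferrin, was the only called erythroid gene and fell from 7957 ± 1677 to 4369 ± 1076 (adjusted p = 0.0486; the call was lost in 9 of 10 such fits, up to 0.145 without wild-type replicate 2). Interferon-stimulated genes (22 measured, median 0.0987, adjusted p = 0.574), T and NK cell markers (5 measured, median 0.187, adjusted p = 0.722), mast cell and basophil markers (5 measured, median 0.00874, adjusted p = 0.885) and endothelial markers (18 measured, median 0.0358, mean -0.0104, adjusted p = 0.911) had no call. The medians of the interferon, mast cell and endothelial lists turned negative when arrays were centred on the median.

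**Figure D3:**
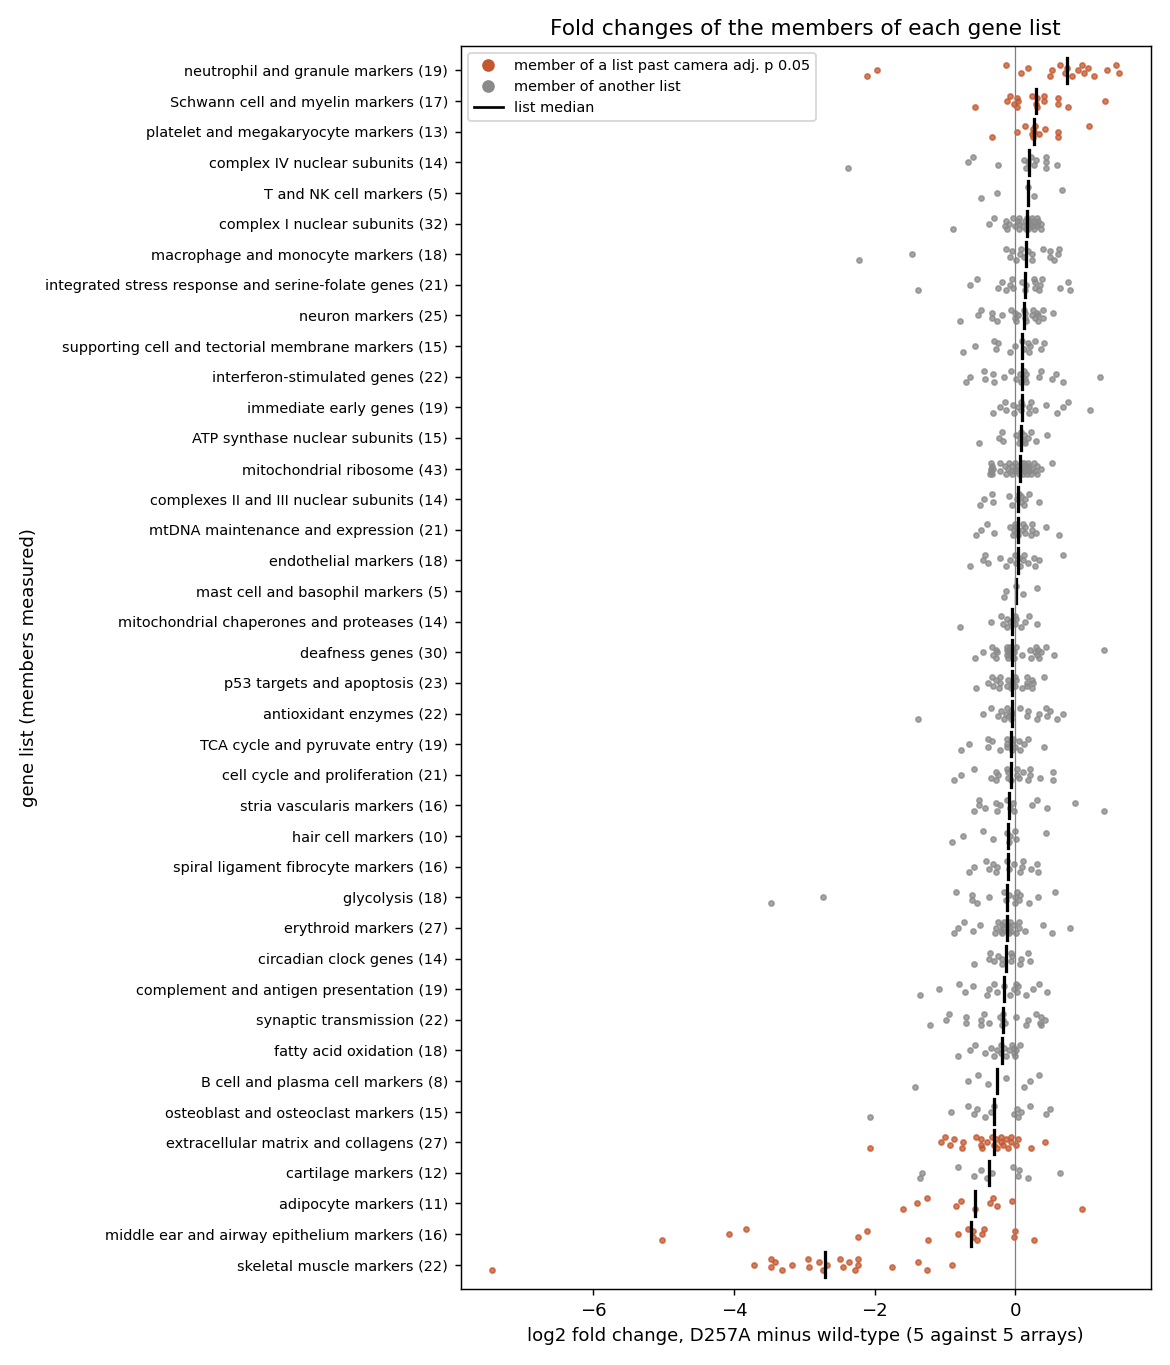
Log2 fold change (D257A minus wild-type, 5 against 5 arrays) of each measured member of the 40 lists, 1 point per gene, with a bar at each list's median. Points in red belong to the 7 lists past an adjusted camera p of 0.05; the medians run from -2.71 for muscle to 0.733 for neutrophil markers.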

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

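The tests on muscle markers, central against peripheral myelin and neutrophil against erythroid markers were chosen after the values were seen; the other tests were stated before their results were known, though after the patterns themselves had been seen.

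In 428 groups of 5 arrays (174 genes and 40 list scores in each genotype), 24 had 1 array far from the others by Dixon's ratio (the gap to the nearest array over the range, on log2 values or scores), where chance gives about 1 in 20, or 21.4. Wild-type replicate 3 stood apart for 8 of the 18 genes. It was low for Ndufa9 (6054.8, others from 10536; ratio 0.739), Sdha (19200.3, others from 28157.1; 0.98), Dlst (4210.2, others from 7307; 0.759), Pdhx (926.7, others from 1818.6; 0.755), Echs1 (1832.2, others from 4971.9; 0.744) and Polg (1972.8, others from 2887.2; 0.775), and high for Cox6a1 (76561, others up to 59142.5; 0.729) and Hbb-b2 (4234.5, others up to 2181.9; 0.794). Wild-type replicate 4 was low for Fpr2 (691.7; 0.72), Ctsg (498.6; 0.773) and Hdc (390.6; 0.732), and wild-type replicate 1 for Lipf (8034.8; 0.754). D257A replicate 5 was low for Gp2 (55.4; 0.782), Gria4 (2045; 0.906), Ank1 (11824.7; 0.753) and Scd1 (10146; 0.716). D257A replicate 4 was low for Usp18 (987.7; 0.851) and high for Col3a1 (7884.4; 0.712).

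Among list scores, D257A replicate 2 was low for mitochondrial chaperones and proteases (-0.361; ratio 0.748), neuron markers (-0.424; 0.751), bone markers (-0.446; 0.766) and cartilage markers (-0.456; 0.817). D257A replicate 1 was low for interferon-stimulated genes (-0.064; 0.824), and wild-type replicate 1 high for p53 targets and apoptosis (0.0865; 0.726).

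Muscle, gland and skin transcripts form a pattern: they were lower in D257A. If the D257A samples held less adjoining tissue, other gland and epidermis genes should fall and cochlear markers stay: 10 gland genes had a median of -0.554 (SE 0.395 over genes) and 8 epidermis genes -0.824 (SE 0.199), so the higher of these medians was -0.554, while the 4 cochlear lists lay between -0.102 and 0.0998. None of these gland and epidermis genes stands in the fixed lists. A genotype effect on gland and skin genes would lower them too, so their fall does not tell these causes apart. Of the cochlear lists, that of hair cells had 8 of 10 markers negative and a mean of -0.223. The brightest gland gene, Wfdc2, measured 12710 ± 3470 in wild-type and 5936 ± 1841 in D257A, and the brightest epidermis gene, Krt10, 3873 ± 1409 and 1424 ± 461.3. Less of the same muscle would lower all muscle markers by 1 factor, but Myh2 fell further than the others. Its change minus the median change of the 21 other markers, against the wild-type mean, was -3.29 or below in 5 of 5 D257A arrays. In the wild-type arrays this difference was -0.459 or above. In D257A replicate 2, for example, Myh2 changed by -6.96 and the others by -1.79. Myh2 was picked as the gene with the largest fall, and its D257A signals (18 to 486.4) lay below 577. This gene alone therefore does not decide whether there was less of the same muscle. For the other markers that also stays open. The interquartile range of their changes was above all wild-type arrays in 5 of 5 D257A arrays (0.76 to 2.23, against at most 0.663), but this range can widen with the depth of the fall, since genes also expressed elsewhere fall less, and only D257A replicate 5 (-0.601) had a median fall no deeper than wild-type replicate 3 (-1.45). A genotype effect on muscle transcripts cannot be told apart from a difference in which muscle was taken: 1 D257A array, replicate 5, had over 50% of the 22 markers (12) reach the lowest wild-type value, against at most 2 markers in the others. Less adjoining tissue may account for part of this pattern, and so may a genotype effect. The deeper fall of Myh2 rests on 1 gene picked for its size.

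Another pattern is the rise of brain-type transcripts such as Ttr and Mobp. More choroid plexus in the D257A samples is in line with 12 other choroid plexus genes, whose median was 0.486 (SE 0.18), although Aqp1 was called lower and 1 of the 12 also stands in a fixed list. The array scores of that list were 0.499 and 0.722 in D257A replicates 2 and 5. Those of replicates 3 and 4 (-0.00614 and -0.0492) lay somewhat above the wild-type range of -0.282 to -0.142, and that of replicate 1 (-0.159) within it. The choroid plexus transcript Ttr, seen before, measured 8513 ± 2500 and 94330 ± 56810. It measured 11273.8 in D257A replicate 4 but 88267.7 and 81369.5 in replicates 1 and 3, where the list rose little or not at all. The brightest gene of the list, Igfbp2, measured 6466 ± 1747 and 12740 ± 7661. More central nerve root cannot be told apart from a general rise of myelin genes. The median of 11 measured central myelin genes exceeded that of 8 measured peripheral ones by 0.146, with an exact permutation p of 0.111 for the array scores. Of the 16 central and 13 peripheral genes listed, measured or not, 8 and 7 also stand in the fixed lists. A lower share of the other tissues would raise all brain-type markers alike, but 13 other cerebellar genes had a median of -0.496 (SE 0.335). The exact permutation p of their array scores was 0.0635. This cannot decide the question, since cerebellar scores varied widely within wild-type. Wild-type replicate 1 scored -0.977, below all D257A arrays, and the other wild-type arrays 0.373 to 1.06. A fall had also been seen before in Pcp2, Car8, Gabra6 and Neurod1. A biological change of glia or choroid plexus with genotype was not tested.

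The last pattern is the rise of neutrophil and cytokine transcripts. More blood or marrow of unchanged makeup is argued against by the neutrophil minus erythroid score, 0.625 higher in D257A (exact permutation p of 0.0397), with 20 of 27 erythroid markers negative. This is not firm. The 7 positive ones include the haemoglobin gene Hbb-b2 (log2 fold change 0.78, limma adjusted p = 0.157) and Ank1 (0.53, adjusted p = 0.0949). The difference of these scores was already visible in the lists, and in D257A replicate 4 it was -0.322, near the wild-type mean of -0.313. An inflammatory response is in line with 13 other cytokine response genes, whose median was 0.797 (SE 0.233; camera adjusted p of 0.000449, 0.208 with an estimated correlation). Its brightest gene, Nfkbia, measured 31350 ± 6902 and 60810 ± 20310. The array scores of that list were 1.24 and 1.16 in D257A replicates 2 and 5 and -0.39 in replicate 4, and the exact permutation p of 0.0635 does not pass 0.05, so the rise may rest on those arrays. Marrow of another makeup was not tested.

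Chance alone is an unlikely source of the 513 changed probe sets. Of 100 drawn splits of the 10 arrays into 5 and 5, only 1, the real one, gave as many. The highest other gave 6. This takes the arrays as separate animals, which the labels do not say outright. For the number of shifted lists, 7, chance cannot be excluded, as 42 of 100 splits gave as many and the highest other gave 13. Some of these splits keep most arrays in their real groups, and the number does not judge any single list. The extracellular matrix list, for example, also passed with an estimated correlation and with fry.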

How the results depend on the processing

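The estimates without both least correlated arrays were chosen after seeing the data; all others were planned. The 513 changed probe sets (233 higher, 280 lower, 275 genes) and 7 lists (3 higher, 4 lower) stayed within 1.5 times under both other pseudocounts, quantile normalization and no intensity trend, and a fold over 1.5 left the probe sets at 513. Median centring gave 479 lower. The brightest 30% gave 322 probe sets, 131 higher, with fewer tested. Array weights gave 1217 (590 higher, 627 lower, 661 genes); the cause was not tested. An unmoderated per-probe-set test gave 3719 at unadjusted p under 0.05 and a fold over 1.1 (1817 changed probe sets, higher, and 1902 changed probe sets, lower), and 165 after Benjamini-Hochberg (68 and 97). An adjusted p under 0.30 gave 3913 (1911 and 2002). Without both least correlated arrays there were 574 probe sets (410 of them shared) and 8 lists.

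With an array left out, probe sets ranged from 168 to 574, higher ones from 72 to 296, lower ones from 94 to 291, changed genes from 84 to 306, lists from 7 to 9, higher lists from 3 to 5 and lower lists from 3 to 5. With an estimated correlation 1 list passed (0 higher, 1 lower). No filter gave 7 lower lists and the mean over probe sets 5 higher ones; the cause was not tested. No filter on list members is the same setting as no filter.

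The sample numbers did not pair the arrays: the correlations of deviations within numbers were 0.183, -0.214, -0.337, 0.148 and 0.181, and 1 of 5 wild-type arrays correlated best with its own number. The replicate block gave 188 probe sets (74 higher, 114 lower, 113 genes). Of the 55 called named genes 39 kept their call under it, and immediate early genes passed as a list (adjusted p = 0.0474). All 55 called named genes kept their direction in every setting that gave a value, and no called value reversed. Signal over background limits what can be tested: detection calls were not used here, and the lower edge of tested signals was 577.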

Other observations

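The genes and tests given here were chosen after values had been seen, apart from the epidermis, gland, choroid plexus, cerebellar and cytokine response lists, which were written before their members' values were looked at.

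Further transcripts differed in the same limma fit. Actc1, cardiac actin, fell from 3727 ± 1518 to 406.9 ± 72.04 (SD, n = 5 each; adjusted p = 0.000179). The epidermal genes Krt1, Lor and Sbsn fell with log2 fold changes of -2.70, -2.65 and -2.84 (adjusted p = 0.00318, 0.000896 and 0.00107). Igha, an immunoglobulin heavy chain, fell from 4738 ± 2396 to 906.9 ± 154.5, and Car8, a Purkinje cell transcript, from 9148 ± 5645 to 1120 ± 746.5 (adjusted p = 0.048). Ddit4, a stress-induced inhibitor of mTOR signalling, rose from 4735 ± 1110 to 12560 ± 4203 (adjusted p = 0.0133), and the chemokine gene Cxcl2 from 304.4 ± 133.1 to 9181 ± 10410 (adjusted p = 0.046). The D257A means of Actc1 and Krt1 and the wild-type mean of Cxcl2 lay below 577, so the sizes of these changes are uncertain. The cochlear transcript Coch measured 74290 ± 6934 and 68700 ± 8933 (adjusted p = 0.705).

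Of the 7 lists written later, each passed camera, and none passed with an estimated correlation: the adjusted p-values were 0.0893 for gland, 0.101 for epidermis, 0.211 for cerebellum, 0.174 for choroid plexus, 0.208 for cytokine response, 0.062 for central myelin and 0.174 for peripheral myelin. Exact permutation of the array scores, in both directions, gave p of 0.0238, 0.00794, 0.0635, 0.0238, 0.0635, 0.00794 and 0.167 in the same order, where 0.00794 is the smallest that 5 against 5 arrays can give. The cerebellar score of wild-type replicate 1 was -0.977, below those of all other wild-type arrays (0.373 to 1.06).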
